A study of Mus musculus with 20 samples.

How the data were processed

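Total RNA from 2 mouse pools was measured on 20 arrays of the GE Healthcare (Amersham) CodeLink type, a 1-colour platform on which biotin-labelled RNA is hybridised to a single array. Per the labels, one pool was adult retina of C57/B6 mice and the other was cortex of Swiss-Webster mice at postnatal day 1. Each pool was run on 5 arrays at a first site and on 5 arrays at site 2, which gave 4 groups of 5 arrays. The arrays of a group are called technical replicates in the labels. The retina and the cortex pools differ in tissue, strain and age at once, so a difference between them cannot be assigned to any of these. The number of arrays limits the precision, and with arrays of the same RNA a p-value measures only the spread between arrays, not between animals.

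The deposited table holds 1 intensity per probe and array for 10500 probes, on a linear scale, and its 20 columns were matched to the 20 arrays. Labelling followed the CodeLink Expression Assay, per the labels' protocols. The scanner software, background correction, scaling and quality filter are not given in the sources used here. From the values, the intensities appear to be background-subtracted, since 143 were at or below 0, and divided by a constant for each array, since the array medians ran from 0.927 to 0.963. The absolute scale therefore has no unit, and 1 corresponds to about the median probe. The table had 2080 blank values. No detection call was used here, so a low intensity cannot be told from background by a flag. No 2 arrays held identical values.

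Probes were named from the platform annotation. Of the 10500 probes, 9378 had 1 gene symbol, 8 had several and 1114 had none, and the last 2 kinds were tested but not named. The Entrez identifiers of 9323 probes were found in a RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names only and changed 0 symbols. The named probes stood for 9230 genes, 145 of them with several probes. For a gene with several probes, the probe with the highest mean log2 intensity over the 20 arrays stood for the gene. Among the 141 such genes with several tested probes, 0 had probes called in opposite directions between retina and cortex at the first site.

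Intensities were put on the log2 scale, with values at or below 0 treated as missing. A probe was tested if it had a value on at least 3 of the 5 arrays in each group, which kept 10339 probes and left out 161. The medians of the log2 values differed between arrays by at most 0.0594. This lay under the limit of 0.1 set beforehand, so the deposited scaling was kept with no further normalization. Log2 differences of dim probes are compressed or inflated by the unknown background step, and the floor settings named at the end of this section address this.

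Differences were tested with limma 3.58.1 in R 4.3.3. One linear model with a mean for each of the 4 groups was fitted to all 20 arrays (lmFit), and the variances were moderated across probes (eBayes, 16 residual and 2.16 prior degrees of freedom). The 5 contrasts taken from it were retina minus cortex at the first site, the same at site 2, the difference between those, and site 2 minus the first site for each tissue. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over the 10339 probes of a contrast. A probe was called when the adjusted p was under 0.05 and the difference was at least 2-fold, because technical replicates make very small differences significant. The spread within groups was summarised as the SD of log2 intensity over the 5 arrays of each probe. It was compared between groups through each array's median absolute distance from the mean of the other arrays of its group, by an exact 2-sided permutation test of 5 against 5 arrays, adjusted over 4 tests. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.

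Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, adjusted over 28 lists at 2 sites. The lists covered rod phototransduction, cone phototransduction, photoreceptor outer segment and structure, the visual cycle, retinal transcription factors, bipolar cells, amacrine and horizontal cells, retinal ganglion cells, the ribbon synapse, Müller glia, pigment epithelium and melanocytes, lens and crystallins, cortical projection neurons, cortical interneurons, neural progenitors, immature neurons and axon growth, the cell cycle, ionotropic glutamate receptors, GABA and glycine receptors, the oligodendrocyte lineage, microglia and macrophages, endothelial cells, erythroid cells, connective tissue and meninges, glycolysis, oxidative phosphorylation, ribosomal proteins and sex chromosome markers. Missing values, 0.362% of the total, were replaced by the group mean for camera only. The 28 lists were fixed before the data were examined, as were the groups, the tests, the thresholds and the rule for naming genes. A further 5 short marker lists (pituitary, hypothalamus, striatum, thalamus and choroid plexus) were added after the data were seen for the closing section.

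The rule named the 10 genes with the largest and the 10 with the smallest mean log2 retina-cortex difference among genes called in the same direction at both sites. From each list it took the 2 most extreme members in the direction of the list's median and 1 at the other end. From each comparison of sites it took the 3 called genes with the largest and the 3 with the smallest difference, and it allowed list members whose retina-cortex difference was called different between the sites. This gave 108 genes. Other list members appear only as examples within counts and were chosen after their values were seen.

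The fit was tested on simulated data with the real probe means and spreads and 50 probes changed at each of 4 fold sizes in each comparison. For retina against cortex at the first site, 46%, 94%, 96% and 96% of the probes changed 2-, 3-, 4- and 8-fold were recovered, with 1 wrong call among unchanged probes. The shares were 42%, 90%, 98% and 100% with 0 wrong calls at site 2, and 42%, 78%, 90% and 94% with 3 wrong calls for the difference between sites. They were 44%, 92%, 98% and 96% with 1 wrong call for the sites in retina, and 52%, 96%, 94% and 98% with 3 wrong calls in cortex. A true change of 2-fold equals the size threshold, so many such changes are missed by construction. The camera step, run on 100 simulated lists for the first site, found the 1 shifted list and 0 others. Simulated probes varied independently, without correlated genes or shifts of a whole array, so errors from those are not covered. Far fewer probes were changed than differed between the real retina and cortex, which makes the adjusted p stricter. Each probe also had the same spread in all groups. The shares and wrong calls therefore describe the simulated setting and need not hold for the real comparisons.

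The same replicate numbers occur in all groups. The labels do not tie a number to a shared day or hybridisation, so arrays were not paired. The alternatives were centring each array on its median, quantile normalization, leaving out the 30% dimmest probes, a floor at the 5th percentile of positive intensities (0.0448), probes with all 20 values only, no size threshold, an intensity trend in eBayes, a replicate block, a fit of only the 2 groups compared, the mean of all probes of a gene, an estimated correlation in camera, and each array left out in turn. A floor at the 25th percentile (0.195) was added after the data were seen.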

Results

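Expression was measured in RNA of adult mouse retina and of newborn mouse cortex, each aliquoted from 1 pool and run on 5 arrays at each of 2 sites. Per the design text the 5 replicates served to assess variation within the platform, and the second site variation across sites. The 20 arrays fell into 4 groups of 5. Array medians ran from 0.927 to 0.963 intensity units, and the number of arrays limits the precision. The first-site arrays had 22 to 39 blank values each and the site 2 arrays 152 to 217. The brightest probe of an array read 98.4 to 125.0 at the first site and 166 to 272 at site 2. The 5 arrays of a group are technical replicates of the same RNA, so p-values measure only the spread between arrays. Retina and cortex also differed in strain and age, so differences between them are those of adult C57/B6 retina against postnatal day 1 Swiss-Webster cortex.

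By mean difference over the 2 sites, among genes called at both, Fabp12, Rp1 and Sag led towards retina and Nts, Gh and Sox11 towards cortex. Fabp12, a fatty acid binding protein of the retina, was 274-fold higher in retina at the first site (log2 difference 8.10, SE 0.52) and 626-fold higher at site 2 (9.29, SE 0.52). Opn1mw, the medium-wavelength cone opsin, was 172-fold and 173-fold higher, and Gnat2, the cone transducin, 227-fold and 149-fold (7.22 log2 at site 2, and 8.13 without cortex replicate 5 of site 2). In the other direction Nts, the precursor of neurotensin, read 21.6 in cortex and 0.0728 in retina at the first site (SD 0.15 and 0.29 log2, n = 5 each), a log2 difference of -8.22 there and -7.80 at site 2. Gh, growth hormone, was 189-fold and 142-fold higher in cortex. In limma, 2574 of 10339 probes (24.9%) were called at the first site, 1229 higher and 1345 lower in retina, and 2542 (24.6%) at site 2, 1144 higher and 1398 lower. Of these, 905 and 842 differed at least 4-fold.

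The 10 genes with the largest mean difference towards retina were Fabp12, Rp1, Sag, Gnat1, Mgarp, Rom1, Gnat2, Tulp1, Susd3 and Opn1mw. Sag is rod arrestin, Gnat1 is rod transducin, and Rp1, Rom1 and Tulp1 are proteins of photoreceptors. Susd3 was 114-fold and 268-fold higher in retina. The 10 with the largest difference towards cortex were Nts, Gh, Sox11, Neurod6, Avp, Fabp7, Myc, Mki67, Pbk and 1500035N22Rik. Avp, the precursor of vasopressin, was 48.3-fold and 43.7-fold higher in cortex, and Myc, a transcription factor of proliferating cells, 38.7-fold and 41.3-fold. Neurod6, a transcription factor of cortical excitatory neurons, was 71.1-fold and 77.2-fold higher. Sox11, a factor of newborn neurons, was 81.6-fold and 81.2-fold higher by its brighter probe, while a dimmer probe of Sox11 differed by -0.12 and -0.31 and was not called. Pbk, a mitotic kinase, was 49.1-fold and 26.4-fold higher, and 1500035N22Rik 48.4-fold and 20.3-fold. These 20 genes had adjusted p of 6.9e-09 or less in limma at both sites, apart from Gnat2 at site 2 (2.3e-08). Of the named genes called, 75 of 76 at the first site and 76 of 79 at site 2 had every array of the higher tissue above every array of the lower one, and the exceptions were Tra2a at both sites and Cmtm2a and Dct at site 2. The Cmtm2a call (-4.59) was lost without cortex replicate 2 (-3.08) or 3 (-3.01) of site 2 and with only the 2 groups compared (adjusted p in limma 0.083, 0.084 and 0.086). Tra2a differed by 1.42 and 1.05, and its first-site call was lost without retina replicate 1 (0.96), its site 2 call without any of 8 arrays (adjusted p in limma up to 0.114) and with a replicate block (adjusted p = 0.064). The lower group often read near the 5th percentile of all intensities (0.0448), so the largest folds depend on an unknown background step.

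**Figure D1:**
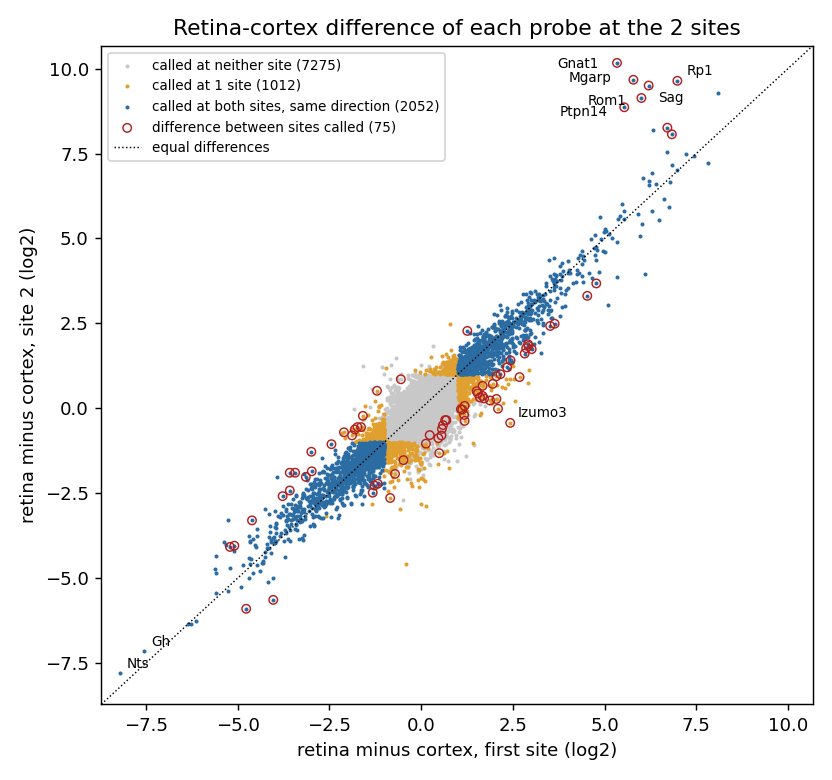
Each point is 1 of 10339 probes, with the log2 retina minus cortex difference at the first site on the x axis and at site 2 on the y axis. The 2052 probes called at both sites in the same direction follow the dotted line of equal differences, and Gnat1 (5.34 and 10.17), Mgarp, Sag, Rom1, Rp1 and Ptpn14 lie above it.

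Phototransduction genes were higher in retina as groups. Of 10 rod phototransduction genes measured, 9 were called higher in retina at each site and 0 lower, and adjusted over the list alone 10 and 9 were. Sag read 92.7 in retina and 1.26 in cortex at the first site, a 73.7-fold difference, and 726-fold at site 2. Gnat1 was 40.5-fold and 1152-fold higher. Gnat1 was the brightest probe of first-site retina replicate 5 (121) and of site 2 retina replicate 2 (166), and Sag came close to the maximum on other retina arrays. A ceiling in retina was not excluded, and the site 2 folds rest on dim cortex values, so the size of these folds is uncertain. Gucy2e, a photoreceptor guanylate cyclase, missed the call (1.09 and 0.97 log2, adjusted p = 0.061 and 0.093 in limma), and it passed at the first site in 3 other settings and at site 2 after quantile normalization (1.25). On retina replicate 2 of site 2 Gucy2e read 4.89, against at most 0.438 on the other 4 arrays, and without it the site 2 difference was 0.26. The rod list as a whole was higher in retina in limma's camera (median 4.48 and 4.58 log2, adjusted p = 5.0e-06 and 8.8e-07), also with an estimated correlation (adjusted p = 0.0026 and 0.0016). All 5 cone genes measured were higher in retina at both sites (median 7.22 and 7.22, adjusted p = 1.2e-04 and 1.9e-04), and with an estimated correlation (adjusted p = 0.039 and 0.043). The smallest was Cngb3, a subunit of the cone cyclic nucleotide channel, at 7.55-fold and 3.70-fold. Outside the rod list at the first site, each list gave the same count adjusted over the list alone as over all genes tested.

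Genes of the outer segment and of photoreceptor structure were called higher in retina in 11 of 12 cases at the first site and 12 of 12 at site 2. Rp1, a microtubule protein of the outer segment, was 127-fold and 799.7-fold higher, and Rom1, a disc membrane protein, 64.2-fold and 563-fold. Impg1, a matrix protein around photoreceptors, was the smallest (1.72-fold, not called at the first site, and 2.16-fold at site 2). The list passed camera (median 5.16 and 5.15 log2, adjusted p = 1.8e-09 and 1.2e-09) and did so with an estimated correlation (adjusted p = 0.019 and 0.017). Some transcripts of this list and of the rod list stood higher in cortex at the first site than at site 2, Gnat1 at 2.66 against 0.141, Sag at 1.26 against 0.202 and Rom1 at 0.835 against 0.205, while others, such as Rcvrn and Rpgrip1, did not. The visual cycle, which regenerates the chromophore, had 4 of 6 genes higher at each site, led by Rpe65, the retinoid isomerase (24.8-fold and 31.8-fold), and Rdh5 (18.9-fold and 15.4-fold), while Rbp4 differed by -0.59 and -0.50 and was not called. Its camera result (adjusted p = 0.0027 and 0.0070) was lost with an estimated correlation (adjusted p = 0.081 and 0.114 with an estimated correlation).

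Many genes of other retinal cell types were higher in retina, but not all. Of 8 retinal transcription factors, 5 were called higher at each site, among them Neurod4 (85.1-fold and 97.2-fold) and Otx2 (21.2-fold and 22.5-fold), and Lhx4 was not (0.23 and 0.12 log2). The list passed camera at both sites (adjusted p = 4.1e-04 and 1.9e-04, and 0.017 at each with an estimated correlation). Of 5 bipolar cell genes, 3 and 4 were higher, led by Pcp2 (44.2-fold and 64.2-fold) and Gng13 (10.6-fold and 12.8-fold), while Trpm1 differed by 0.22 and 0.49. The bipolar list passed camera (adjusted p = 0.0013 and 3.1e-04), and with an estimated correlation at site 2 only (adjusted p = 0.051 and 0.032 with an estimated correlation). Amacrine and horizontal cell genes were higher in 7 of 10 cases at each site, with Pvalb, parvalbumin, at 4.38 and 3.90 log2 and Slc18a3, the vesicular acetylcholine transporter, at 2.74 and 2.82, and Tfap2a was not called (-0.09 and -0.48). That list passed camera (adjusted p = 4.0e-04 and 0.0024, and 0.017 and 0.029 with an estimated correlation). Of 9 ganglion cell genes, 7 and 5 were higher, led by Sncg, gamma-synuclein (46.5-fold and 47.5-fold), and Nefh, the heavy neurofilament (11.8-fold and 14.1-fold), while Slc17a6 differed by -0.29 and 0.05. The ganglion cell list passed camera (adjusted p = 6.1e-04 and 0.0015, and 0.017 and 0.025 with an estimated correlation).

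Ribbon synapse genes were higher in 3 of 5 cases at each site, with Stx3 30.2-fold and 31.9-fold and Ctbp2, which encodes the ribbon protein RIBEYE, 4.86-fold and 5.49-fold, and Pclo was not called (-0.35 and -0.66). Their camera result (adjusted p = 0.0070 and 0.0074) was lost with an estimated correlation (adjusted p = 0.114 and 0.116 with an estimated correlation). Müller glia genes were higher in 7 of 11 cases at each site (camera adjusted p = 2.8e-04 and 2.1e-04, and 0.017 at each with an estimated correlation). Their leading members were Spc25, known as a kinetochore component (21.0-fold and 24.9-fold), and Car2, carbonic anhydrase 2 (4.00 and 4.32 log2), and Sox9 was not called (-0.05 and -0.26). Lens and crystallin genes were higher in 5 and 4 of 9 cases, led by Cryba4 (7.42-fold and 7.78-fold) and Cryab (5.98-fold and 6.32-fold), while Mip differed by 0.31 and -0.93 (-0.12 at site 2 without cortex replicate 5 of site 2). The lens list passed camera (adjusted p = 0.0013 and 0.0096), at site 2 not with an estimated correlation (adjusted p = 0.032 and 0.072 with an estimated correlation). Of 7 genes of pigment epithelium and melanocytes, 3 and 2 were higher in retina and 1 was higher in cortex at each site. Krt18 was 40.4-fold and 29.5-fold higher and Dct 13.9-fold and 6.55-fold (2.71 log2 at site 2, and 3.37 without cortex replicate 5 of site 2), and Oca2 was 2.78-fold higher in cortex at the first site but not called at site 2, where Ttr, chosen after its value was seen, was (-1.27). The pigment list did not pass camera (adjusted p = 0.232 and 0.546).

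Glycolysis genes were higher in retina in 12 of 16 cases at the first site and 13 at site 2, and 0 were higher in cortex. Hk2, hexokinase 2, read 28.9 in retina and 0.880 in cortex at the first site (SD 0.10 and 0.31 log2, n = 5 each) and was 32.8-fold and 37.4-fold higher. Aldoa, aldolase A, was 8.11-fold and 7.37-fold higher, whereas Pfkm, muscle phosphofructokinase, differed by 0.46 and 0.42 and was not called. The list passed camera (median 1.70 and 1.82 log2, adjusted p = 7.0e-09 and 3.8e-09, and 0.017 at each with an estimated correlation). Oxidative phosphorylation did not (adjusted p = 0.546 and 0.953): 0 of 22 genes were called at the first site, and only Sdha, a succinate dehydrogenase subunit, at site 2 (1.19 log2, and 0.97 after quantile normalization). At site 2 the list's median was -0.06 while camera ranked it towards retina. Sdhb (-0.43 and -0.69) and Ndufs4 (-0.52 and -0.71) were not called.

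**Figure D2:**
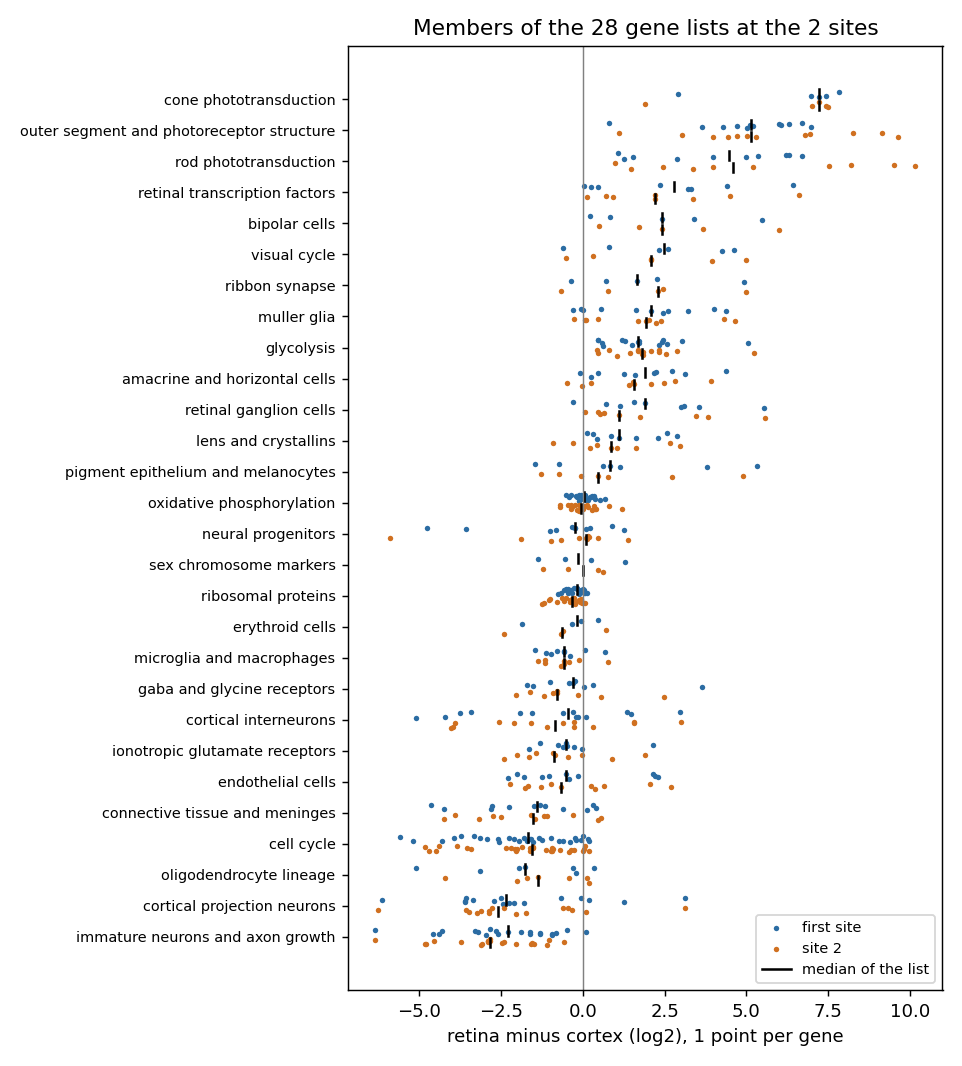
Each point is 1 gene of a list, placed on the x axis by its log2 retina minus cortex difference at the first site (upper row of a list) or site 2 (lower row), with black bars at the medians. The cone list lies farthest to the right (median 7.22 at each site), and immature neurons (-2.29 and -2.86) and projection neurons (-2.36 and -2.60) farthest to the left.

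Genes of immature neurons and axon growth were higher in cortex in 16 of 21 cases at the first site and 20 at site 2, and 0 were higher in retina. Sox11 read 12.6 in cortex and 0.154 in retina at the first site. Marcksl1, a regulator of the actin cytoskeleton, was 23.9-fold and 28.7-fold higher in cortex, and Dcc, a netrin receptor, was not called (0.09 and -0.59). The list passed camera (median -2.29 and -2.86, adjusted p = 5.4e-09 and 2.6e-10, and 3.9e-04 and 3.4e-04 with an estimated correlation). Cell cycle genes were higher in cortex in 20 and 18 of 30 cases, and 0 were higher in retina. Mki67, the proliferation marker Ki-67, was 48.6-fold and 28.6-fold higher and Top2a, topoisomerase 2 alpha, 36.9-fold and 25.8-fold, while Ccna2 differed by 0.20 and 0.19. The cell cycle list passed camera (median -1.67 and -1.56, adjusted p = 6.4e-07 and 8.4e-07, and 3.4e-04 at each with an estimated correlation). Neural progenitor genes did not pass (adjusted p = 0.251 and 0.581): of 11, 3 and 2 were higher in cortex and 1 in retina. Fabp7, a fatty acid binding protein of radial glia, was 27.3-fold and 59.9-fold higher in cortex and Emx2 differed by -3.58 and -1.90 (-0.38 at site 2, not called, with a floor at the 25th percentile), and Msi1 was 2.39-fold and 2.62-fold higher in retina. At site 2 the median of this list was 0.08 while camera ranked it towards cortex.

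Cortical projection neuron genes were higher in cortex in 11 of 16 cases at each site and in retina in 2 and 1. Neurod6 led, followed among the named genes by Tbr1, a factor of deep-layer neurons (12.2-fold and 11.3-fold). Neurod1, which photoreceptors also express, was 8.67-fold and 8.72-fold higher in retina. The list passed camera (adjusted p = 1.0e-04 and 7.0e-06), at the first site not with an estimated correlation (adjusted p = 0.052 and 0.032 with an estimated correlation). Of 14 interneuron genes, 6 and 7 were higher in cortex, such as Lhx6 (34.1-fold and 16.5-fold) and Dlx1 (18.5-fold and 15.9-fold), and 3 were higher in retina at each site, such as the neuropeptide gene Vip (7.80-fold and 8.01-fold). The interneuron list passed camera at site 2 only (adjusted p = 0.067 and 0.042), a call lost with an estimated correlation (adjusted p = 0.299 and 0.256 with an estimated correlation) and without cortex replicate 5 of site 2 (adjusted p = 0.0556).

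Among receptors, Gria2 was 3.13-fold and 5.33-fold higher in cortex and Grik1 4.44-fold and 3.74-fold higher in retina. Of 10 ionotropic glutamate receptor genes, 2 and 4 were higher in cortex and 1 in retina, and the list did not pass camera (adjusted p = 0.232 and 0.122). Grin2b was called at site 2 only (-2.03 log2), and it differed by -1.27 without cortex replicate 5 of site 2 and by -0.84, not called, with a floor at the 25th percentile. Of 9 GABA and glycine receptor genes, 3 were higher in cortex at each site, among them Gabrb1 (3.30-fold and 4.11-fold) and Gabrg1 (2.87-fold and 2.26-fold). Gabrr1, a GABA receptor subunit of retina, was 12.5-fold and 5.62-fold higher in retina, and this list did not pass either (adjusted p = 0.381 and 0.153).

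Genes of connective tissue and meninges were higher in cortex in 8 and 9 of 12 cases, and 0 were higher in retina. Lum (-4.65 and -3.92 log2) and Dcn (-4.25 and -4.24), both matrix proteoglycans, led, and Sparc was not called (0.39 and 0.55). The list passed camera (adjusted p = 0.0096 and 0.011, and 0.029 and 0.031 with an estimated correlation). Oligodendrocyte lineage genes were higher in cortex in 4 of 7 cases at each site, led by Olig1 (34.4-fold and 18.6-fold) and Sox10 (8.83-fold and 4.06-fold), while Mog, a late myelin gene, differed by 0.33 and 0.12. This list passed camera (adjusted p = 0.013 and 0.029), at site 2 not with an estimated correlation (adjusted p = 0.043 and 0.067 with an estimated correlation). Microglia genes were higher in cortex in 2 and 3 of 9 cases, among them Fcer1g (2.76-fold and 2.25-fold) and Aif1 (2.17-fold and 2.22-fold), and Ctss differed by 0.68 and 0.78 without being called. Their camera result (adjusted p = 0.035 and 0.031) was lost with an estimated correlation (adjusted p = 0.182 at each site with an estimated correlation).

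Endothelial genes went both ways, with 3 and 2 of 11 higher in retina and 5 and 4 higher in cortex (camera adjusted p = 0.471 and 0.861). Slc2a1, the glucose transporter of vessels and neural tissue, was 4.92-fold and 6.51-fold higher in retina, and Cldn5, a tight junction protein, 4.05-fold and 4.64-fold higher in cortex, as was Tie1 (4.94-fold and 3.40-fold). Among 4 erythroid genes, Hba-a1, alpha globin, was 3.63-fold and 5.32-fold higher in cortex and Ermap (0.46 and 0.69) and Slc4a1 (-0.32 and -0.68) were not called (camera adjusted p = 0.606 and 0.387). Ribosomal protein genes had 0 of 23 called at the first site (median -0.18, adjusted p = 0.145) and 4 higher in cortex at site 2 (median -0.32, adjusted p = 0.0074, but adjusted p = 0.398 with an estimated correlation). Rpl10, which stood near the maximum of the first-site cortex arrays, differed by -0.76 and -1.26, Rplp0 by -0.34 and -1.18 and Rps15 by 0.13 and 0.07, and Rplp0 was not called at site 2 after quantile normalization (-0.94). After that normalization the list passed at the first site as well (adjusted p = 0.0088). Of 4 sex chromosome markers, Xist, transcribed from the inactive X, was higher in cortex at each site (2.61-fold and 2.33-fold), and of the Y-linked genes Uty was higher in retina at the first site (1.28, but 0.70 and not called with a floor at the 25th percentile) but not called at site 2 (0.63), and Eif2s3y was not called (-0.56 and -0.45). The sex chromosome list did not pass camera (adjusted p = 0.903 at each site).

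At site 2 and at the first site the same tissue differences were called for the most part. In total 2052 probes were called at both sites in the same direction, 963 higher and 1089 lower in retina, where independent calls would give 318. They were 67.0% of the 3064 probes called at either site, and 0 probes were called in opposite directions. By gene, 884 were higher and 1016 lower at both sites. Across probes, which are not independent replicates, the differences correlated with r = 0.919 and rho = 0.845. In the 2585 dimmest probes r was 0.701, against 0.951, 0.965 and 0.959 in the 3 brighter bins of equal size. Of the 522 probes called at the first site only, 500 had the same sign at site 2, and of the 490 called at site 2 only, 467 had it at the first.

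The size of the retina-cortex difference was itself different between the sites for a few genes, photoreceptor genes among them. Gnat1 differed by 4.83 more at site 2 than at the first site (log2, SE 0.49), Mgarp, a mitochondrial protein, by 3.89 (SE 0.49) and Ptpn14, a tyrosine phosphatase, by 3.33 (SE 0.35). Their adjusted p in limma were 4.6e-05, 2.5e-04 and 4.8e-05, and on each of the 5 first-site cortex arrays these genes read above all 5 site 2 cortex arrays. Sag (3.30), Rom1 (3.13), Rp1 (2.66) and Tulp1 (1.55), all photoreceptor genes, and Susd3 (1.23) also differed more at site 2. In the other direction were Izumo3 (-2.86), Tspan1 (-2.11), Cdc25c (-1.81) and Sla (-1.61). Among list members, the difference towards cortex was larger at site 2 for Tubb2b (-1.17) and Fabp7 (-1.13) and smaller for Emx1 (1.16), Emx2 (1.68), Sox10 (1.12) and Lhx6 (1.04), and the difference towards retina was smaller for Isl2 (-1.27), Gabrr1 (-1.15) and Cngb3 (-1.03). Gnat1 stood near the maximum on all 5 first-site retina arrays and Sag on 2, and Mgarp, Ptpn14, Rom1, Rp1 and Tulp1 read within 2-fold of the lowest of these maxima (98.4). Tubb2b stood near the maximum on all 5 first-site cortex arrays and Fabp7 on replicate 5. A first-site ceiling was therefore not excluded as a source of part of these 9 values. When single arrays were left out, the call of Cngb3 was lost with any of 16, of Emx2 with 10, of Gabrr1 with 10 (-0.86 without cortex replicate 5 of site 2), of Lhx6 with 3 (0.94 at the lowest) and of Sox10 with 1 (0.98 without retina replicate 4 of site 2). Also lost were the calls of Lhx6 (0.63), Cngb3 (-0.77) and Gabrr1 (-1.04) and of Tubb2b (-0.35), Fabp7 (-0.75), Sox10 (0.89) and Isl2 (-0.99) after quantile normalization. With a replicate block the call of Cngb3 was lost (adjusted p = 0.085 in limma), and with a floor at the 5th percentile those of Emx1 (0.95) and Lhx6 (0.99). A floor at the 25th percentile (0.195) ended the calls of Izumo3 (-0.87), Tspan1 (-0.76), Cdc25c (-0.32), Sla (-0.70), Rp1 (1.07, adjusted p = 0.112 in limma) and Susd3 (0.41). Rp1 and Susd3 read 0.0624 and 0.0920 in site 2 cortex, below that floor. It also ended those of Emx1 (0.79), Emx2 (0.90), Sox10 (0.57), Lhx6 (0.60), Isl2 (-0.53) and Cngb3 (-0.83).

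In limma 75 probes were called for this difference, 28 higher and 47 lower, and 411 at adjusted p alone. After quantile normalization the split was 38 higher and 41 lower. Without cortex replicate 5 of site 2 the count was 121. From the dimmest to the brightest of 4 equal bins of probes, 29, 25, 11 and 10 of the 75 calls fell.

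**Figure D3:**
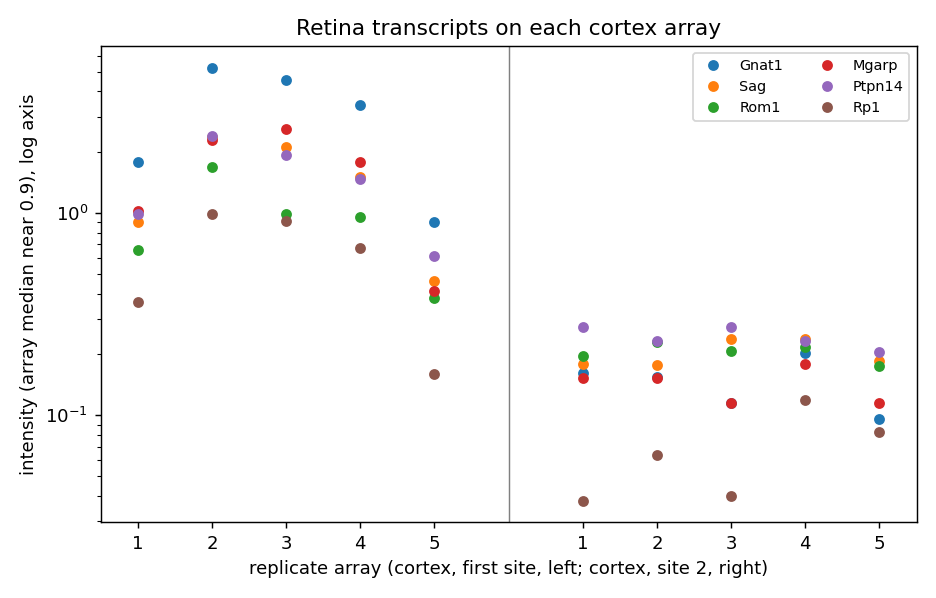
The intensity of 6 retina transcripts (y axis, log scale, array medians near 0.9) is plotted for each of the 10 cortex arrays (x axis, replicate numbers, first site left and site 2 right). On the first-site arrays Gnat1 runs from 0.905 to 5.24, and at site 2 it lies between 0.0954 and 0.203.

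The retina pool gave values at least 2-fold apart at the 2 sites for a small share of probes, while many more differed by less. Stk32c, a kinase, rose by 2.73 (log2) from the first site to site 2, Dppa2 by 2.71 and Tra2a, a splicing factor, by 2.65. Lcp2, an adaptor protein of blood cells, differed by -3.11, Izumo3 by -2.39 and Sla by -2.36. In limma these had adjusted p between 5.0e-11 (Lcp2) and 9.2e-04 (Dppa2), and for each of them all 5 arrays of one site lay above all 5 of the other. Dppa2 read 0.0130 at the first site, below the 5th percentile of all intensities, and with a floor at that percentile it differed by 0.93 and was not called. With a floor at the 25th percentile the call of Izumo3 was lost (-0.87). Among genes of the lists, Sncg (-1.12, but -0.87 and not called after quantile normalization) and Slc2a1 (-1.23) fell, and Sox9 (1.34) and Sox10 (1.33, but 0.77 and not called with that floor) rose, while Rom1 rose by 1.10 and the other rod and outer segment genes among the named ones were not called. In all 645 of 10339 probes (6.24%) were called in limma, 495 higher at site 2 and 150 lower, and 4825 (46.7%) had adjusted p below 0.05 at any size; the split of calls was 298 and 176 after quantile normalization.

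The cortex pool showed a change of similar extent. Slc38a2, an amino acid transporter (3.41), and Stk32c (3.21) rose from the first site to site 2, and Gnat1 (-4.23), Mgarp (-3.26) and Rp1 (-3.04) fell. Sag (-2.64), Ptpn14 (-2.46), Rom1 (-2.03), Fabp12 (-1.70) and Tulp1 (-1.44) fell with them, and Gh fell by 1.07. Cmtm2a had the largest mean rise (4.85), but from 2 arrays alone. For all of these but Cmtm2a and Fabp12 the 5 arrays of one site lay above the 5 of the other, and adjusted p in limma ran from 3.9e-08 (Gnat1) to 0.017 (Cmtm2a). Cmtm2a read 29.0 and 33.2 on replicates 2 and 3 of site 2 and 0.0539 and 0.048 on 2 others, against 0.0434 at the first site (SD 5.34 log2 over 4 site 2 arrays). Without replicate 2 or 3 of that group Cmtm2a differed by 3.35 and 3.28 and was not called (limma adjusted p = 0.075 and 0.076), nor with only the 2 groups compared (adjusted p = 0.085). Fabp12 was not called with only the 2 groups compared (adjusted p = 0.069 in limma) or with a floor at the 25th percentile (-0.49). Gh was not called after quantile normalization (-0.93), nor was Mip (1.17), which also missed with that floor (0.66) and with only the 2 groups compared (adjusted p = 0.102 in limma). Gh (-0.99) and Mip (0.82, against 1.63) missed the size threshold without cortex replicate 5 of site 2, and Mip also missed the call without first-site cortex replicate 1 or 3 (adjusted p in limma 0.061 and 0.052). In all 745 probes were called in limma, 547 higher at site 2 and 198 lower, and 4841 (46.8%) had adjusted p below 0.05 at any size; the split of calls was 251 and 259 after quantile normalization.

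Some of the site changes were shared by the 2 tissues. Lcp2 fell in both (-3.11 in retina and -2.98 in cortex), as did Sncg (in retina not after quantile normalization) and Slc2a1, and Stk32c, Tra2a, Slc38a2, Dppa2 and Sox9 rose in both. In cortex the rise of Dppa2 (1.82) was not called without first-site cortex replicate 1 (1.31) or 2 (1.63), with a floor at the 5th percentile (0.69) or after quantile normalization (1.36, adjusted p = 0.051 in limma). In limma 1120 probes were called in either tissue. Of these, 269 were called in the same direction in both, 188 higher and 81 lower at site 2, where independent calls would give 29.1. Another 1 was called in opposite directions. Across probes the changes correlated with r = 0.686 and rho = 0.697. The 2 changes share no arrays. The dimmest of 4 equal bins of probes held 279 of the 645 calls in retina and 309 of the 745 in cortex. The correlation was not adjusted for brightness.

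Replicate arrays differed little within a group, and dim genes varied most. Over all tested probes the median SD of log2 intensity was 0.162 in retina and 0.165 in cortex at the first site, and 0.158 and 0.225 at site 2. In the dimmest of 10 equal bins of probes it was 0.530 to 0.552 and in the brightest 0.110 to 0.169. Among the named genes, Otx2 in retina at site 2 had an SD of 0.04 at an intensity of 12.9, and Mog in cortex at the first site 1.32 at 0.0368. The distances of arrays from their groups were not shown to differ in any of 4 exact permutation tests of 5 against 5 arrays, which can reach 0.00794 at the least. Exact here means that every regrouping was enumerated. The 5 distances of a group depend on each other, since each is taken from the mean of the other arrays, so these p-values are approximate. Cortex against retina gave 0.0081 at the first site (exact p = 0.659, adjusted 0.878) and 0.0647 at site 2 (exact p = 0.143, adjusted 0.429). Site 2 against the first gave 0.0022 in retina (exact p = 0.881, adjusted 0.881) and 0.0588 in cortex (exact p = 0.214, adjusted 0.429). Leaving out 1 array turned the sign of each of the 4 (to -0.00856, -0.0170, -0.0144 and -0.0229 at the lowest). Without replicate 1, 2 or 3 of site 2 cortex both comparisons with that group passed after adjustment (exact p = 0.0159 or less), and without replicate 5 neither did. Cortex replicate 5 of site 2 correlated with its group at 0.918 to 0.923, where the other 4 correlated at 0.984 to 0.992 with each other, and without it the median SD of the group was 0.132. On that array Gnat2 read 1.47, Pvalb 2.19 and Gabrr1 2.51, above the other 4 arrays of its group (at most 0.0721, 0.415 and 0.959). Over arrays, r had a median of 0.968 between the sites for retina and 0.877 to 0.899 between retina and cortex.

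**Figure D4:**
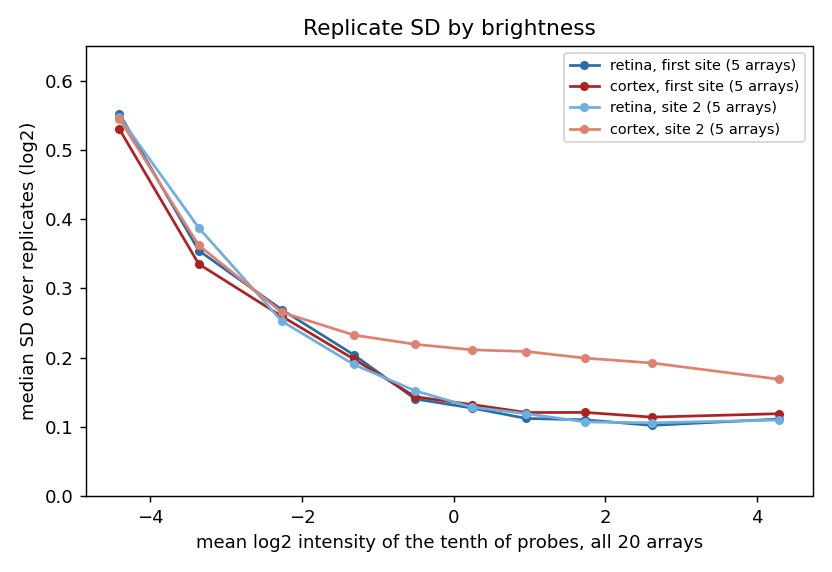
The median SD of log2 intensity over the 5 arrays of a group (y axis) is plotted against the mean log2 intensity of each of 10 equal bins of probes (x axis), with 1 line for each of the 4 groups. The SD lies between 0.530 and 0.552 in the dimmest bin, and in the brightest cortex at site 2 stands at 0.169 against 0.110 to 0.119 in the other groups.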

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

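The tests on photoreceptor transcripts and on cortex replicate 5 of site 2 were chosen only after those results were seen, while the counts of other splits were planned. For the probe-response test, the choice of probes and the bound were also set after the values were seen. The intervals given below for median log2 values were bootstrapped over probes, not over arrays. They leave out the spread between arrays and are therefore too narrow. A group was listed here when the gap of its highest or lowest array to the nearest other array, divided by the group's range, was above Dixon's 95% critical value. Chance gives this in about 1 in 20 groups, so in 21.05 of the 421 groups of named genes tested, and 40 were found. Of these, 17 lay on cortex replicate 5 of site 2 and 6 on retina replicate 2 of site 2.

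Among the array summaries, this ratio was 0.793 for the array median in the first-site cortex group. In the site 2 cortex group it was 0.799 for the distance from the other arrays and 0.922 for the correlation with them, and replicate 5 was the array apart in both (distance 0.392, r 0.925).

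On cortex replicate 5 of site 2 the lowest value of the group was that of Aldoa (ratio 0.766), Car2 (0.820), Dlx1 (0.782), Lhx6 (0.740), Olig1 (0.751), Pfkm (0.775), Rps15 (0.743), Sdhb (0.796), Sncg (0.732) and Tbr1 (0.718). The highest was that of Dct (0.937), Gabrr1 (0.916), Gnat2 (0.920), Grin2b (0.830), Mip (0.915), Myc (0.789) and Pvalb (0.894). Over all tested probes the median log2 difference of this array from the mean of the other arrays of its group was -0.339. Low values on it were therefore not particular to the genes listed. On retina replicate 2 of site 2 the highest value was that of Ccna2 (0.759), Dct (0.860), Gucy2e (0.953), Rps15 (0.725) and Tie1 (0.844), and the lowest that of Mki67 (0.747). On the other site 2 retina arrays the ratios were 0.741 for Gabrb1, 0.802 for Rom1, 0.770 for Sdha, 0.750 for Sox10, 0.724 for Stk32c, 0.771 for Susd3 and 0.767 for Tulp1. In the first-site retina group they were 0.778 for Cmtm2a, 0.792 for Ctbp2, 0.776 for Emx1 and 0.716 for Xist. In the first-site cortex group they were 0.760 for Fabp7, 0.797 for Oca2, 0.838 for Olig1, 0.753 for Sla, 0.719 for Sparc and 0.712 for Stk32c.

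The retina-cortex difference itself differed between the sites, by limma's test of the interaction, for 21 named genes. At site 2 minus the first site the log2 values were 4.83 for Gnat1, 3.89 for Mgarp, 3.33 for Ptpn14, 3.30 for Sag, 3.13 for Rom1, 2.66 for Rp1, 1.55 for Tulp1 and 1.23 for Susd3. They were 1.68 for Emx2, 1.16 for Emx1, 1.12 for Sox10 and 1.04 for Lhx6. They were -2.86 for Izumo3, -2.11 for Tspan1, -1.81 for Cdc25c, -1.61 for Sla, -1.27 for Isl2, -1.17 for Tubb2b (near the first-site maximum in cortex, as Gnat1 and Sag were in retina), -1.15 for Gabrr1, -1.13 for Fabp7 and -1.03 for Cngb3.

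Photoreceptor transcripts such as Gnat1, Sag and Rom1 stood higher on the first-site cortex arrays than at site 2, and a little retina RNA on those arrays may account for it. Over 44 probes bright in retina and low in site 2 cortex the 5 arrays fell in 1 common order (Kendall W 0.600, against 0.0658 at the 95th percentile of 10000 matched random sets, permutation p = 1e-04, the smallest they can give). The excess had a median of 0.605% of the first-site retina level over the 44 probes (-2.05% to 3.50%) and of 1.37% over the 10 brightest (-0.247% to 2.81%). A ceiling on the first-site retina arrays would raise the share of the brightest probes, and any other site change of a probe in cortex also enters the excess. Whether 1 constant share describes it therefore cannot be told. These probes were chosen for a low value in site 2 cortex, and the excess is taken over that same value. A positive excess was thus favoured by the choice and does not measure an amount of retina RNA. A higher background is argued against, since 1944 dim probes rose by 0.484 (0.456 to 0.506) in cortex from the first site to site 2. A site difference in probe response stays open: the 11 probes called lower in cortex (median -2.03) differed by 0.112 in retina (-0.506 to 0.662, bound -1.01), but 8 of them read within 2-fold of the lowest first-site retina maximum (98.4), where saturation can hide a fall, all 44 probes changed by -0.03 in retina (-0.35 to 0.15) and 19 moderately bright ones by -0.28 beside -0.34 in cortex, and no biological explanation was tested because the RNA was the same.

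On cortex replicate 5 of site 2, 551 probes were raised over the rest of the group, against at most 164 on any other array. Retina RNA is argued against, since the raised probes had a median first-site retina-cortex difference of -0.00216 (-0.0833 to 0.0423). A swap is argued against too, since the array correlated with its own group at a median of 0.922 and with arrays of the other groups at 0.907 or less. The raised probes bunched by probe number (variance over mean 8.003 per 100 probe numbers, at most 1.53 in 10000 random placements, with 89.3% of them in a range that held 43.0% of the tested probes). A signal bound to a stretch of the slide is a candidate explanation, but how probe numbers relate to slide positions is not given in the sources used here, and no biological explanation was tested.

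For 4 comparisons, the count was set against those of arbitrary groupings of the same arrays. Only 1 of 100 splits of the arrays, the real one, gave as many calls. Every other split mixed 2 tissues or 2 sites within a group, which widens the spread within groups. That favoured the real split beforehand, so its rank is not a strong test of chance. The result therefore covers the spread between arrays only, not between animals or pools. The real count and the highest of the other splits were 2574 and 975 for retina against cortex at the first site, 2542 and 976 at site 2, 645 and 87 for the sites in retina and 745 and 124 in cortex. For the difference between sites 3 of 100 joint splits, the real one among them, gave at least the real 75 calls (3%, exact interval 0.623% to 8.52%). The share lay under 5 in 100, but its interval, which counts the real split, did not. Another draw can give another count. These splits also mixed the sites within each tissue, which breaks the site changes along with the difference between sites. They therefore do not measure how many of the 75 calls chance can give, and chance is not excluded for this comparison. The highest had 1943 calls and points to a structure of the samples: it exchanged all 5 retina arrays between the sites but kept 4 of 5 cortex arrays, so that site effects shared by the tissues added instead of cancelling. The next, with 94, kept all 5 retina arrays and 3 of 5 cortex arrays, and the highest of the rest had 22.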

How the results depend on the processing

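All settings were planned except the floor at the 25th percentile, which was chosen after seeing the data. Of 5623 values of named genes under other settings, 5492 stayed on the same side of the threshold, 124 no longer passed and 7 newly passed. Among values that passed in either setting 0 reversed direction. Direction was not compared for values that passed in neither. Of 1454 list values 1440 stayed on the same side of the threshold, 13 no longer passed and 1 newly passed. Without the 30% dimmest probes 43 calls were made for the difference between sites, 315 for the sites in retina and 383 in cortex, as fewer and brighter probes were tested, and the median SD was 0.124 and 0.131 in first-site retina and cortex and 0.126 in site 2 retina. With the floor at the 25th percentile the sites in retina gave 313 calls and in cortex 396, since differences below the floor are removed by construction. With no size threshold the counts were 6192 and 6247 for retina against cortex, 411 for the difference between sites, 4825 and 4841 for the sites and 5110 for probes called at both sites. Leaving out 1 array gave 56 to 121 calls for the difference between sites, the highest without cortex replicate 5 of site 2. The spread of cortex against retina at site 2 ran from -0.0170 to 0.101 and of site 2 against the first site in cortex from -0.0229 to 0.0949, the lowest without that array, and the cause was not tested. The median SD of site 2 cortex ran from 0.132 to 0.244. The counts for retina against cortex stayed within 2521 to 2611 and 2499 to 2585. After quantile normalization the higher and lower calls were 298 and 176 for the sites in retina (495 and 150 as reported), 251 and 259 in cortex (547 and 198) and 38 and 41 for the difference between sites (28 and 47), so the excess of calls higher at site 2 in cortex depends on the scaling. With a replicate block the counts were 2573, 2535, 63, 638 and 737, and 38 lists passed. Arrays of the same number correlated between groups at -0.0784 to 0.0536 after removing group means. Deposited values with no further normalization were the values reported and gave no separate result. Signal over background limits the dimmest probes, whose differences depend on the unknown background step.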

Other observations

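The marker lists of this part were added after the data were seen, and the tests on Gh and Avp were written before their markers' values were seen, except that the need for an exact interval to exclude the bound was added afterwards. Some genes of other brain regions also differed between the pools. Tcf7l2, a transcription factor of thalamic neurons, was higher in cortex (-4.49 at the first site, SE 0.18, and -4.09 at site 2, SE 0.18), as were Lhx9 (-1.30 and -1.25) and Prkcd (-1.21 and -1.47), while Rora, which retina also expresses, was higher in retina (3.53 and 2.66). Of 7 thalamus markers 3 were higher in cortex at both sites and 1 in retina. Of 4 striatum markers 0 were higher in cortex and 2 in retina, Drd2, a dopamine receptor (2.47 and 2.79), and Ebf1 (1.56 and 1.05). Of 3 choroid plexus markers 0 were higher in cortex at both sites and 2 in retina, Aqp1, a water channel (3.82 and 3.41), and Folr1 (1.45 and 1.31), and Ttr, which is also in the pigment list, was called higher in cortex at site 2 only (-0.74 and -1.27).

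Gh and Avp, hormone genes of pituitary and hypothalamus, were among the genes highest in the cortex pool relative to retina. RNA of the pituitary may be present in the pool, but of 7 other pituitary markers measured 1 was called higher in cortex at both sites (14.3%, exact interval 0.361% to 57.9%), namely Cga (-3.67 and -3.03). Pomc (-0.14 and -0.45) and Prl (-0.54 and 0.04) were not called in either direction, and Chga (1.10 and 1.01) was called higher in retina at both sites. Over all 9084 genes tested, 1016 were higher in cortex at both sites. Prl read 0.0358 to 0.0582 in the 4 groups and Pitx1, also among the 7 markers, 0.0276 to 0.0476. Both lay near the 5th percentile of all intensities (0.0448), so they say little either way. How abundant the marker transcripts are in newborn pituitary was not examined. The share lay under the bound of 25% set beforehand, yet the interval reaches over 50%, so 7 markers do not decide. RNA of the hypothalamus stays open as well, with 2 of 5 markers higher in cortex at both sites (40%, exact interval 5.27% to 85.3%), Pmch (-4.69 and -3.75) and Hcrt (-2.89 and -2.09). Ghrh (-1.01 and -1.52) was called higher in cortex at site 2 only. Gal (-0.53 and -0.36) and Sim1 (-0.34 and -0.54) leaned the same way without being called. Expression in newborn cortex itself was not tested.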
